A study of Mus musculus with 4 samples.

How the data were processed

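Polysome RNA of mouse ADSCs was sequenced in 4 libraries, 2 labelled scrambled and 2 labelled IFIT1 knockdown. Per the labels' protocols, RNA was harvested with Trizol, messenger RNA was captured on beads and fragmented by heat, and cDNA was end-repaired, A-tailed, ligated to adapters and size-selected on beads. The values used are FPKM (fragment numbers scaled to gene length and library depth), computed by the authors and named as FPKM in the sample labels. The submitters' processing notes name the genome builds GRCm38, mm10 and GRCm39 without saying what each was used for. The aligner, the counting tool, the annotation, the strandedness and the handling of reads that match several genes are not given in the sources used here, and no coordinates are printed. All 4 value columns were used and 0 were left out.

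The sums of FPKM were 598188 and 616504 in the libraries labelled scrambled and 701936 and 680137 in those labelled knockdown, so the values are not scaled to a common total. Within each library FPKM are whole fragment numbers times a constant of the library and of the gene. Relative depths of 1.0000, 1.2145, 1.2252 and 1.1241 (libraries labelled scrambled 1, scrambled 2, knockdown 1 and knockdown 2) were found from the ratios of low values. Each gene's smallest whole fragment numbers were then solved for, with a relative tolerance of 3e-08, an absolute tolerance of 1e-06 and rounding of the last decimal of 6e-10, and numbers up to 60000 were tried. Whole fragments were recovered for 15872 genes and for 8693 (99.3%) of the tested genes. The method was tested on simulated data, where 593 of 599 genes (99.0%) were recovered exactly, apart from a common divisor. A gene's true fragment numbers can therefore be a multiple of those given. Fragment numbers served for depth, counting error and the checks named here, and counting error is all they cover, since copies made by PCR are not independent molecules.

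Genes with a mean FPKM of at least 1 over the 4 libraries were tested, 8750 of 18200. Values were taken as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) compared the 2 libraries of each group without a batch term. P-values are two-sided and adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The degrees of freedom came to 3.06 per gene and the smallest adjusted p was 1.6e-04. Spread is given as SD with n = 2. The replicate number and the batch in the labels coincide, so the within-batch difference pairs the replicates by the labels' shared batch. The pairing was checked by correlating, across 8750 genes, the difference between replicates 1 and 2 in both groups: Pearson's r was -0.83, where libraries paired by batch would give a positive value. The unpaired fit had been chosen beforehand, and the fit with batch as a block is an alternative. Other tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

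Genes were named by a rule: the Ifit family, the 10 largest increases and the 10 largest decreases among genes past the threshold with the same sign in both batches, the 4 tested members with the smallest p of each gene list, and Actb and Gapdh. Predicted genes, pseudogenes and genes listed as not protein coding were counted and not named. The rule gave 105 genes, and the few genes outside it are marked in the text as chosen after their values were seen. The 24 gene lists were the Ifit family, interferon-stimulated genes, inflammatory cytokines and chemokines, skeletal myogenic, cardiac and smooth muscle contractile genes, cytosolic ribosomal proteins, translation factors, ATF4 and integrated stress response genes, extracellular matrix genes, angiogenic and paracrine factors, Wnt pathway, cell cycle, senescence and growth arrest, nuclear-encoded oxidative phosphorylation, and glycolysis and hypoxia genes, markers of mesenchymal stromal cells, adipocytes, leukocytes, endothelium, and epithelium and mesothelium, and, for RNA quality, mostly nuclear long noncoding RNAs, mitochondrially encoded and immediate-early stress genes. List symbols were matched to the table by symbol (621 matched, 18 of them through a synonym, and 76 without an entry), which gave 437 tested members. Lists with at least 3 tested members, 20 of them, were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. The same test with an estimated correlation and limma's fry were run as further tests. With the preset correlation 6 lists passed, with an estimated correlation 0 (adjusted p from 0.73 to 0.95), and with fry 9. With an estimated correlation, camera rests on the few residual degrees of freedom of these 4 libraries. Ribosomal proteins had an estimated correlation of 0.00, below the preset 0.01, and still had adjusted p = 0.73 with camera. A miss with an estimated correlation therefore decides little about a list. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance. Members up, down and not past are counted over all tested genes, and again adjusted over the list alone.

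The fit was tested on simulated data: 8693 genes with the recovered depths, a biological CV of 0.1 and 50 changed genes per fold. Of each 50, 8 were called at a fold of 1.25, 32 at 1.5, 49 at 2 and 50 at 4, and 10 of 8493 unchanged genes were called. The simulated replicates were independent, while many genes of the real ones agreed more closely than counting error gives. These rates therefore need not hold for the data. A simulated list that moved had adjusted p = 9.1e-41 and one that did not had 0.51. The simulated counts set beside counting SDs in the results are a separate simulation. They were drawn around each group's own mean with counting error alone and no biological spread.

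The lists, the rule for named genes, the test and these alternatives were chosen before the data were examined: batch as a block, a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-centred values, quantile normalization, limma without trend and with robust fitting, leaving out each library in turn, a log2 change of at least 1, an adjusted p of 0.1, and the further list tests. A test on counts was also chosen and was not run, because the values used are FPKM. After seeing the data, 4 alternatives were added: a block that pairs scrambled 1 with knockdown 2, a standard error not allowed below the counting error of the recovered fragments, limma-voom on the recovered fragments, and the same sign in both batches. The counting error is that of log2 fragments, while the changes are on log2(FPKM + 1), so as a floor it is too strict for genes with low FPKM. Transcript length and GC content for the bias checks came from a GENCODE annotation of GRCm38 and served no other purpose. A smooth trend fitted on genes in no fixed list was taken out of each library. A scan of 810 Reactome terms with 10 to 200 tested members, annotated in the table itself, used the same camera test with its own Benjamini-Hochberg adjustment.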

Results

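RNA taken from polysomes (messenger RNA carrying several ribosomes) of mouse ADSCs, as the labels call the cells, was sequenced in 4 libraries. Total RNA was not among them, so a difference cannot be assigned to the amount of a messenger RNA or to its loading with ribosomes. The series title places the cells among mesenchymal stem cells and asks about Ifit1, translation and muscle differentiation. The labels give 2 libraries as scrambled control and 2 as Ifit1 knockdown by shRNA, with replicate 1 of each group in batch 1 and replicate 2 in batch 2. FPKM values covered 18200 genes, and 14461 and 15677 of them were above 0 in libraries 1 and 2 labelled scrambled, 15500 and 16242 in libraries 1 and 2 labelled knockdown. The values could be turned back into whole fragments for 15872 genes, which summed to 24448952 and 29825482 fragments in the libraries labelled scrambled and to 29011473 and 26466726 in those labelled knockdown. Whether the replicates were separate cultures is not stated, so the p-values measure only the spread between these 4 libraries, which may be technical. Log2 changes are on log2(FPKM + 1) and understate the change of genes with low values.

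Ifit1 (Entrez 15957), the gene named as the target and an interferon-induced protein that binds viral RNA, was higher in the libraries labelled knockdown. Its FPKM was 1.93 and 1.91 in the libraries labelled scrambled and 13.9 and 14.8 in those labelled knockdown. The means were 1.92 ± 0.0149 (SD, n = 2) and 14.3 ± 0.689 (SD, n = 2), a 7.47-fold difference, from 164 and 197 fragments against 1442 and 1416. The log2 change was 2.39 (SE 0.04, limma adjusted p = 1.6e-04), with 2.34 in batch 1 and 2.44 in batch 2. The direction is opposite to the labels, so every direction given here is that of the libraries labelled knockdown against those labelled scrambled, and the labels themselves were not checked by any other value. Ifit3 rose from 0.302 and 0.306 to 4.22 and 4.30 FPKM, and Ifit2 from 2.32 in both libraries to 3.48 and 3.57 (log2 0.45, adjusted p = 2.8e-04). All 3 tested members of the Ifit family list were higher, 3 also when adjusted over the list alone (camera adjusted p = 0.03; adjusted p = 0.8 with an estimated correlation). Ifit3b, below the filter, had 3 fragments in each library labelled scrambled and 108 and 103 in those labelled knockdown. As the smallest whole numbers, Ifit1bl1 had 0, 0, 1 and 2 fragments and Ifit1bl2 had 0, 1, 8 and 8 in the libraries labelled scrambled 1, scrambled 2, knockdown 1 and knockdown 2. Reads of Ifit1 and its close copies can be assigned to either, and how such reads were counted is not given in the sources used here.

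Interferon-stimulated genes rose together in the libraries labelled knockdown. Of 23 tested members of 40 listed, 22 rose, 0 fell and 1 did not pass, with the same 22 and 0 adjusted over the list alone. The other listed genes were below the filter or had no entry. Isg15, a ubiquitin-like protein, rose from 40.8 and 40.2 to 480 and 490 FPKM (log2 3.55, SE 0.02). Irf7, a transcription factor of interferon genes, went from 0.723 and 0.740 to 19.1 and 19.4 FPKM, and Usp18, which removes Isg15 from proteins, from 0.246 and 0.245 to 10.6 and 10.5. Rtp4 rose 8.63-fold. Psmb8, an immunoproteasome subunit, rose 13.0-fold, and Oas1a, a sensor of double-stranded RNA, from 3 and 1 fragments to 1073 and 1087. Reads of Oas1a can be shared with related Oas genes. The member that did not pass was Eif2ak2, which encodes the kinase PKR and is singled out after its values were seen, at 3.66 and 2.69 FPKM in the libraries labelled scrambled and 2.64 and 3.60 in those labelled knockdown. The list's median log2 change was 1.89, with 1.81 in batch 1 and 1.93 in batch 2 (camera adjusted p = 3.2e-10; adjusted p = 0.73 with an estimated correlation). Of 10 inflammatory cytokines and chemokines, 5 rose, 2 fell and 3 did not pass, the same adjusted over the list alone, and the list did not pass (medians of 0.40 in batch 1 and 0.24 in batch 2; adjusted p = 0.14). The chemokine Ccl5 rose from 0.701 and 0.673 to 10.2 and 8.88 FPKM, Cxcl10 rose 3.72-fold and Ccl2 2.30-fold, and the cytokine Lif rose 1.75-fold.

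**Figure D1:**
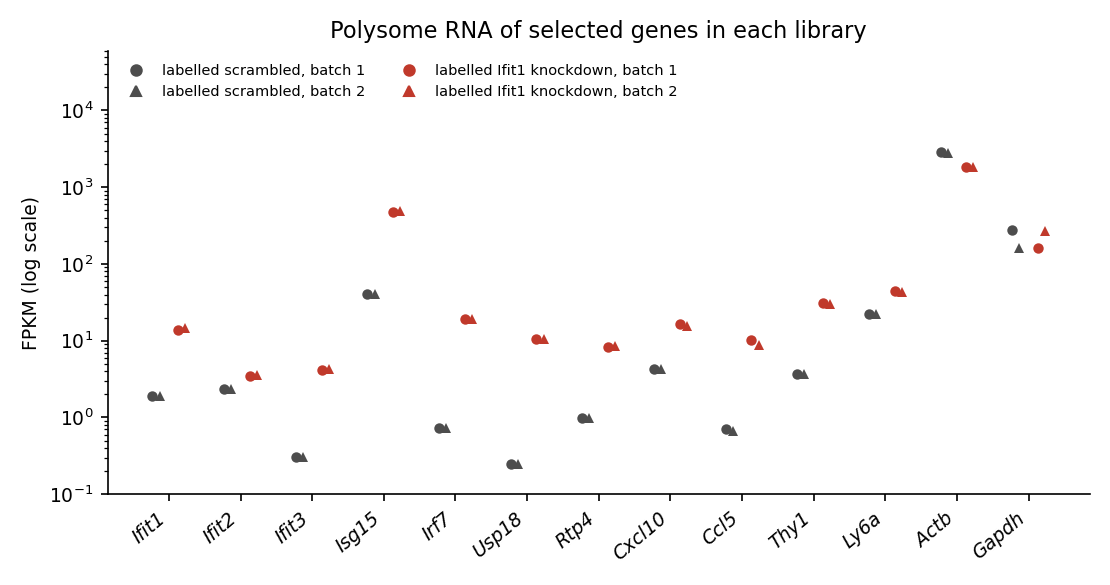
FPKM (log axis) of 13 genes in each of the 4 libraries; grey points are libraries labelled scrambled, red points libraries labelled knockdown, circles batch 1 and triangles batch 2. Ifit1 stood at 1.93 and 1.91 in the libraries labelled scrambled and at 13.9 and 14.8 in those labelled knockdown.

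Of 8750 genes tested, 2401 were higher and 3608 lower in the libraries labelled knockdown, 68.7% of those tested. With a log2 change of at least 1, 412 were higher and 355 lower. All 6009 genes past the threshold had the same sign in both batches. The test fixes this, since a gene with opposite signs in the batches cannot pass it. Of all tested genes, 6519 (74.5%) had the same sign. Centring each library on its median moved the median change of all tested genes from -0.02 to 0.15 and gave 2833 higher and 3040 lower genes. The median difference within a group was 0.54 counting SDs in the libraries labelled scrambled and 0.67 in those labelled knockdown, against 0.68 and 0.66 in simulated counts. From 300 to 1000 fragments it was 0.33 and 0.32 (0.70 and 0.66 simulated), closer than counting error gives, and from 5000 fragments 0.97 and 1.34 (0.64 and 0.66 simulated), wider than it gives. Y-linked genes, chosen after their values were seen, had 3 and 1 fragments in the libraries labelled scrambled and 252 and 307 in those labelled knockdown (Ddx3y, Eif2s3y, Kdm5d and Uty together), the latter 1.40% and 1.45% of the summed FPKM of their X-linked partners, and whether the cells of both groups had the same origin is not stated. The median SE of tested genes was 0.0208, below the median counting SE of 0.0459. The SEs and p-values given here can therefore understate even counting error. With standard errors not allowed below the counting error, a setting chosen after the data were seen, 2072 genes were higher and 3321 lower. Here and below, that floor is too strict for genes with low FPKM. It is the counting error of log2 fragments, while log2(FPKM + 1) shrinks the changes of such genes.

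Besides Irf7, Isg15, Usp18, Psmb8 and Oas1a, 5 genes were among the 10 largest increases. Plac8 rose from 1.00 and 1.03 to 34.6 and 34.7 FPKM, 34.2-fold. Crabp1, which binds retinoic acid in the cytoplasm, rose from 166 and 164 to 2511 and 2537 FPKM, 15.3-fold (log2 3.93, SE 0.02, adjusted p = 1.6e-04). Cdc42ep5, an effector of the small GTPase Cdc42, rose 18.9-fold, and the interferon-inducible Ifi27l2a went from 8 and 10 fragments to 525 and 459. Prxl2b had 1 and 2 fragments in the libraries labelled scrambled and 269 and 242 in those labelled knockdown. Its adjusted p was 0.059 with the counting error as the smallest standard error. That floor is too strict for Prxl2b, whose change on log2(FPKM + 1) is shrunk, so the miss cannot be put down to counting error alone. The largest decrease was in Peg10, an imprinted gene derived from a retrotransposon, from 10.9 and 10.7 to 1.03 and 1.04 FPKM (log2 -2.54, SE 0.02, adjusted p = 1.6e-04). Id2, an inhibitor of basic helix-loop-helix factors, fell to a mean of 10.8 FPKM from 60.1, and Cd24a, a surface glycoprotein, to 3.84 from 20.2. The connexin Gjb2 fell from 6.40 and 6.52 to 0.717 and 0.736 FPKM, and Fbxo32, a ubiquitin ligase subunit of muscle atrophy, from 4.77 and 4.71 to 0.676 and 0.697. The mitochondrial elongation factor Gfm1 fell from 11.6 in both libraries to 2.81 and 2.85 FPKM. Cpne8, the retinal reductase Dhrs3, the homeobox gene Tlx2 and the LIM-domain gene Fhl1 completed the 10, with log2 changes of -1.76, -1.76, -1.76 and -1.70.

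Markers of mesenchymal stromal cells were higher in the libraries labelled knockdown: all 11 tested members of 19 listed rose, 11 also adjusted over the list alone. The other listed markers were below the filter or had no entry. Thy1, a surface antigen of these cells, rose from 3.71 and 3.68 to 31.0 and 30.3 FPKM, 8.29-fold. Ly6a, known as Sca-1, rose 1.96-fold, the hyaluronan receptor Cd44 1.54-fold, and Eng, a TGF-beta co-receptor also on the endothelial list, 2.52-fold. The median log2 change was 0.48, with 0.46 in batch 1 and 0.49 in batch 2 (camera adjusted p = 7.7e-05; adjusted p = 0.73 with an estimated correlation). Among markers of other cell types, epithelial and mesothelial markers had 3 of 5 tested members higher, 1 lower and 1 not past, the same adjusted over the list alone. Krt8, Krt18 and Krt7, keratins of simple epithelia, rose 9.14-fold, 6.15-fold and 3.25-fold from low values, while the far more abundant Krt19 fell from 166 and 161 to 91.4 and 92.2 FPKM, and the list did not pass (medians of 1.04 in batch 1 and 1.07 in batch 2; adjusted p = 0.2). Keratins have pseudogenes that can share their reads. Of 6 adipocyte markers, 2 rose, 3 fell and 1 did not pass, also adjusted over the list alone (medians of -0.17 in batch 1 and -0.53 in batch 2; adjusted p = 0.88): Pparg, the main transcription factor of fat cell formation, fell from 3.02 and 3.15 to 0.961 and 0.998 FPKM, Acsl1 fell by 0.65 and Fabp4 by 0.53 on the log2 scale, and Cebpa rose 1.90-fold. Fabp4 had 73, 85, 50 and 46 fragments. Its adjusted p was 0.097 with the counting error as the smallest standard error, a floor too strict at its low FPKM. Lists with fewer than 3 tested members were not tested as lists. Both endothelial members rose, Egfl7 from 1.68 and 1.61 to a mean of 4.58 FPKM (SD 0.167) and Eng as above. Of the leukocyte members, Cd14 rose from 5.16 and 5.14 to 5.85 and 5.99 FPKM and Coro1a fell from 3.71 and 3.70 to 2.90 and 2.96, with adjusted p = 0.17 and 0.1 with the counting error as the smallest standard error. Cd14 did not pass when the library labelled scrambled 1 or that labelled scrambled 2 was left out (adjusted p = 0.051 each). Coro1a did not pass after median-centring (adjusted p = 0.14) or quantile normalization (adjusted p = 0.051).

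Genes of muscle differentiation were mostly not measured above the filter. Of 5 tested skeletal myogenic genes of 34 listed, 0 rose, 3 fell and 2 did not pass, the same adjusted over the list alone. Mef2d, a MADS-box factor of muscle genes, fell from 11.4 and 11.5 to 6.66 and 6.87 FPKM. Pax3 fell by 0.23 on the log2 scale, but had adjusted p = 0.26 after median-centring. It had 0.19 with the counting error as the smallest standard error, a floor too strict at its low FPKM. Skeletal actin Acta1 did not pass at means of 1.52 (SD 0.145) against 1.17 (SD 0.107) FPKM (adjusted p = 0.062). The list did not pass (adjusted p = 0.26), with medians of -0.54 in batch 1 and -0.22 in batch 2, and camera's direction turned to up without the filter (adjusted p = 0.89). Of 5 tested cardiac genes of 30 listed, 2 rose, 1 fell and 2 did not pass, also adjusted over the list alone (medians of 0.45 in batch 1 and 0.10 in batch 2; adjusted p = 0.37). Tnnt2, cardiac troponin T, rose from a mean of 1.61 to 3.33 FPKM, and the connexin Gja1 rose 1.64-fold. Gata6 passed at a log2 change of -0.16 (adjusted p = 0.035) but not with batch as a block (adjusted p = 0.11), and the change was 0.01 after median-centring. Mef2a did not pass (log2 0.02, adjusted p = 0.78). Of 17 smooth muscle contractile genes, 5 rose, 6 fell and 6 did not pass, the same adjusted over the list alone. Actg2, the enteric smooth muscle actin, rose 3.05-fold, while tropomyosin Tpm1 fell from 439 and 429 to 192 and 195 FPKM and the matricellular genes Ccn1 and Ccn2 fell by 1.53 and 1.09 on the log2 scale. The list had no direction that held across scalings (camera up, adjusted p = 0.88; down after median-centring, adjusted p = 0.93, and after quantile normalization, adjusted p = 0.7), turned down without the library labelled scrambled 2 (adjusted p = 0.9) or knockdown 2 (adjusted p = 0.98), and its medians were -0.19 in batch 1 and 0.12 in batch 2.

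Ribosomal protein genes differed in direction, with more of them higher. Of 79 tested, 36 rose, 9 fell and 34 did not pass, also adjusted over the list alone. Rps14 rose from 4111 and 4028 to 9001 and 8836 FPKM, and Rpl31, Rpl18 and Rpl36a, of the large subunit, rose 1.94-fold, 1.94-fold and 1.87-fold. Ribosomal protein genes have many pseudogenes that can share their reads. The list passed upward (median 0.12, with 0.41 in batch 1 and 0.06 in batch 2; camera adjusted p = 4.4e-04; adjusted p = 0.73 with an estimated correlation), but not after quantile normalization (adjusted p = 0.65). Nuclear-encoded oxidative phosphorylation genes had 25 of 48 members higher, 6 lower and 17 not past, the same adjusted over the list alone. Ndufa2, of complex I, rose 2.36-fold, Uqcrq, of complex III, 1.95-fold and Cox7a2, of complex IV, 1.83-fold, while Sdha, the catalytic subunit of complex II, fell from a mean of 10.9 to 5.73 FPKM. The median log2 change was 0.28, with 0.29 in batch 1 and 0.27 in batch 2 (camera adjusted p = 8.9e-04; adjusted p = 0.73 with an estimated correlation; 0.053 after quantile normalization). Across genes, which are not independent replicates, the log2 change fell with transcript length (Spearman rho -0.41, 8692 genes), and neither list passed once that trend was taken out (adjusted p = 0.99 and 0.62). Of the mitochondrially encoded genes, ND1 rose from 1.10 and 1.04 to 2.20 and 2.14 FPKM and COX1 fell from a mean of 1.29 to 0.806, with adjusted p = 0.087 and 0.24 with the counting error as the smallest standard error; COX1 did not pass without the library labelled knockdown 1 (adjusted p = 0.07) or knockdown 2 (adjusted p = 0.052), nor after median-centring (log2 -0.17 from -0.34, adjusted p = 0.081).

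Translation factors and cell cycle genes were more often lower than higher in the libraries labelled knockdown. So were all tested genes, with 3608 of 8750 lower and 2401 higher. Of 50 translation factors, 5 rose, 27 fell and 18 did not pass, the same adjusted over the list alone. Eif4g1, the scaffold of the cap-binding complex, fell from 67.5 and 66.5 to 29.6 and 30.1 FPKM, Eif2b1, a subunit of the exchange factor of eIF2, from 38.7 and 38.4 to 16.8 and 17.1, and the elongation factor Eef1a1 from 5258 and 5195 to 2697 and 2746. Eif5 fell by 0.90 on the log2 scale. The list did not pass (median -0.24, with -0.41 in batch 1 and -0.27 in batch 2; camera down, adjusted p = 0.086) but did without the filter (adjusted p = 0.0015), after quantile normalization (adjusted p = 0.0045), without the library labelled scrambled 2 (adjusted p = 0.042) and without that labelled knockdown 2 (adjusted p = 0.038). Of 35 cell cycle genes, 2 rose, 21 fell and 12 did not pass, the same adjusted over the list alone. Tpx2, a spindle assembly factor, fell from 41.1 and 39.4 to 14.0 and 14.2 FPKM, Rrm2, a subunit of ribonucleotide reductase, from 109 and 108 to 42.0 and 42.7, the mitotic kinase Aurkb from 51.8 in both libraries to 22.2 and 22.7, and the replication helicase subunit Mcm4 fell by 1.07 on the log2 scale. The list passed downward (median -0.30, with -0.54 in batch 1 and -0.35 in batch 2; camera adjusted p = 0.031; adjusted p = 0.86 with an estimated correlation), but not without the library labelled scrambled 1 or without that labelled knockdown 1 (adjusted p = 0.11 each), nor after the transcript length trend was taken out (adjusted p = 0.083, although the median was then -0.41, SD 0.57 over genes, from -0.30, SD 0.55) or the GC content trend was (adjusted p = 0.074, median -0.32, SD 0.51). With lengths recovered from the values it passed (adjusted p = 0.044). Top2a and Mcm2, chosen after their values were seen, did not pass: Top2a was at 37.0 and 20.5 FPKM in the libraries labelled scrambled and 20.5 and 35.4 in those labelled knockdown, and Mcm2 at 134 and 97.9 against 95.7 and 133.

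In the remaining lists, members moved both ways and no list passed. Of 24 extracellular matrix genes, 8 rose, 11 fell and 5 did not pass, with 9 higher and 11 lower adjusted over the list alone. Collagen I genes fell, Col1a1 from a mean of 20.4 to 6.37 FPKM and Col1a2 from 101 to 34.2, as did the cross-linking enzyme Lox, by 0.95 on the log2 scale, while osteopontin, Spp1, rose 5.72-fold. Camera put that list up (adjusted p = 0.88), its median and mean were -0.02 and -0.08, and camera's direction was down among genes of mean FPKM of at least 5 (adjusted p = 0.94). Of 14 angiogenic and paracrine factors, 4 rose, 4 fell and 6 did not pass (adjusted p = 0.42): the heparin-binding factor Mdk rose 8.07-fold and Ptn 2.05-fold, and Bdnf fell by 0.47 on the log2 scale. Of 11 Wnt pathway genes, 3 rose, 8 fell and 0 did not pass (median -0.60, with -0.62 in batch 1 and -0.57 in batch 2; adjusted p = 0.39): Dvl3, Gsk3b and the transcription factor Lef1 fell by 0.90, 0.78 and 0.81 on the log2 scale, and the receptor Fzd8 rose 3.23-fold. Of 19 senescence and growth arrest genes, 8 rose, 7 fell and 4 did not pass (median -0.03, mean 0.17, camera up, adjusted p = 0.42). The cell cycle inhibitor Cdkn1c rose 3.82-fold, Btg2 and Ccng1 rose 2.66-fold and 2.25-fold, and Sesn1 fell by 1.00 on the log2 scale. Of 26 glycolysis and hypoxia genes, 10 rose, 8 fell and 8 did not pass (median -0.01, mean 0.09, camera up, adjusted p = 0.39): the glucose transporter Slc2a1 rose 2.83-fold, Aldoc 7.59-fold and Bnip3 1.93-fold, and Ndrg1 fell by 0.82 on the log2 scale. Of 22 genes of ATF4 and the integrated stress response, 6 rose, 4 fell and 12 did not pass (median -0.02, mean 0.01, camera up, adjusted p = 0.41): Atf5 and the phosphatase subunit Ppp1r15a rose 1.81-fold and 1.56-fold, and the serine and folate enzymes Psat1 and Mthfd2 fell by 0.93 and 0.91. The counts of these 5 lists were the same adjusted over each list alone, and the angiogenic list had a median of -0.01 and a mean of 0.15. Medians had opposite signs in batch 1 and batch 2 for the extracellular matrix (0.06 and -0.27), angiogenic (0.35 and -0.29), senescence (0.02 and -0.09), glycolysis (-0.26 and 0.36) and ATF4 (0.31 and -0.20) lists.

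Among the measures of RNA quality, 5 of 17 immediate-early stress genes rose, 5 fell and 7 did not pass, the same adjusted over the list alone. Dusp1, a phosphatase of MAP kinases, fell from 45.2 and 45.3 to 18.8 and 19.2 FPKM, Klf6 fell by 0.41 on the log2 scale, the growth arrest gene Btg2 rose 2.66-fold, and Hspa1b, whose reads can be shared with its near-identical copy, fell by 0.53. The list did not pass (camera up, adjusted p = 0.62), its median and mean were both -0.02, with medians of 0.23 in batch 1 and -0.26 in batch 2, and camera's direction was down without the filter (adjusted p = 0.89). The nuclear long noncoding RNA Tug1 did not pass at 1.85 and 2.52 against 2.23 and 1.71 FPKM (log2 -0.10, adjusted p = 0.72), and its change was 0.07 after median-centring. Of the reference genes, Actb fell from 2838 and 2809 to 1809 and 1842 FPKM (log2 -0.63, SE 0.02, adjusted p = 2.0e-04). Gapdh did not pass at 275 and 163 against 161 and 268 FPKM (log2 -0.03, SE 0.43, adjusted p = 0.99; 0.14 after median-centring), with -0.77 in batch 1 and 0.71 in batch 2.

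**Figure D2:**
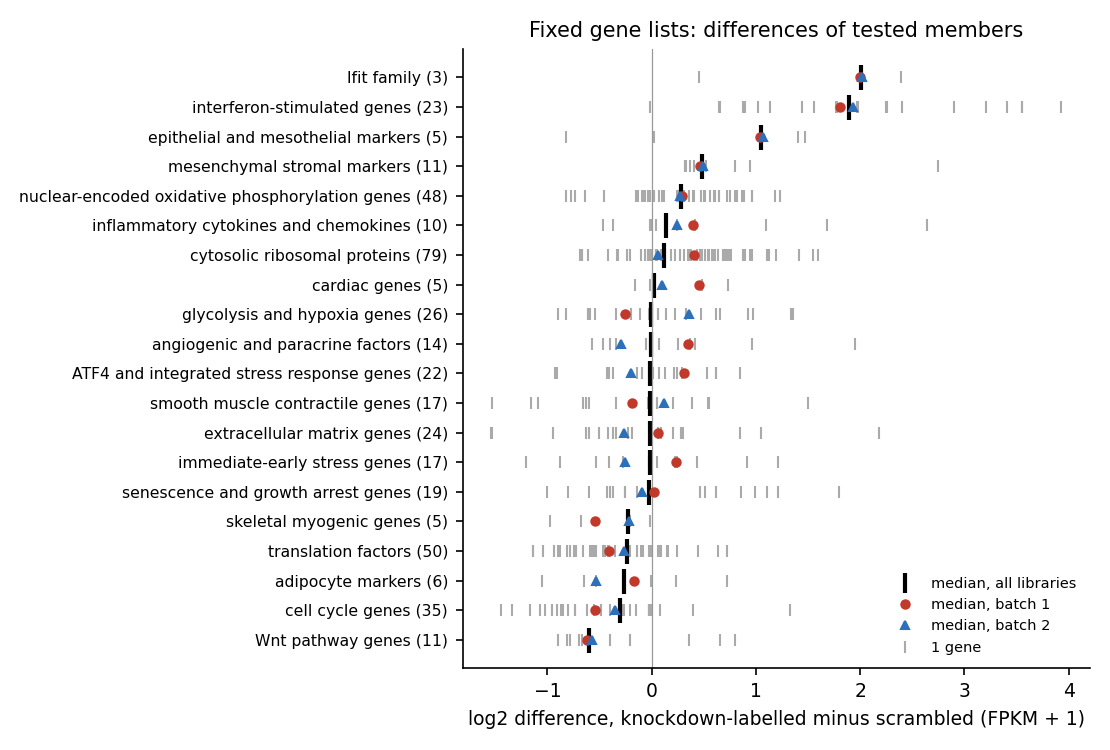
Log2 change (libraries labelled knockdown minus libraries labelled scrambled) of the members of the 20 lists tested; grey ticks are genes, black bars medians over all libraries, red circles medians in batch 1 and blue triangles medians in batch 2, and the number of tested genes is in brackets. The interferon-stimulated genes had a median of 1.89, with 1.81 in batch 1 and 1.93 in batch 2.

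The libraries grouped by label. Across tested genes, which are not independent replicates, Pearson's r was 0.9955 between the libraries labelled scrambled and 0.9950 between those labelled knockdown, 0.9556 and 0.9584 between groups within batch 1 and batch 2, and 0.9613 and 0.9606 between groups across batches. The median absolute log2 difference was 0.025 and 0.029 within groups and 0.481 and 0.457 within batches. Group took 89.1% of the variance and batch 0.9%. The rest lay along the difference between the pair of libraries labelled scrambled 1 and knockdown 2 and the other pair. Gapdh, Top2a, Mcm2 and Eif2ak2 had close values within those pairs and different values between them. Of 8693 genes with whole fragments, 6936 differed in both batches by more than 3 counting SDs, 5546 in the same direction and 1390 in opposite directions. Simulated counts gave 0 in opposite directions. They held counting error alone and no crossing, so that 0 follows from their design. It does not show what ordinary variation between replicates would give.

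**Figure D3:**
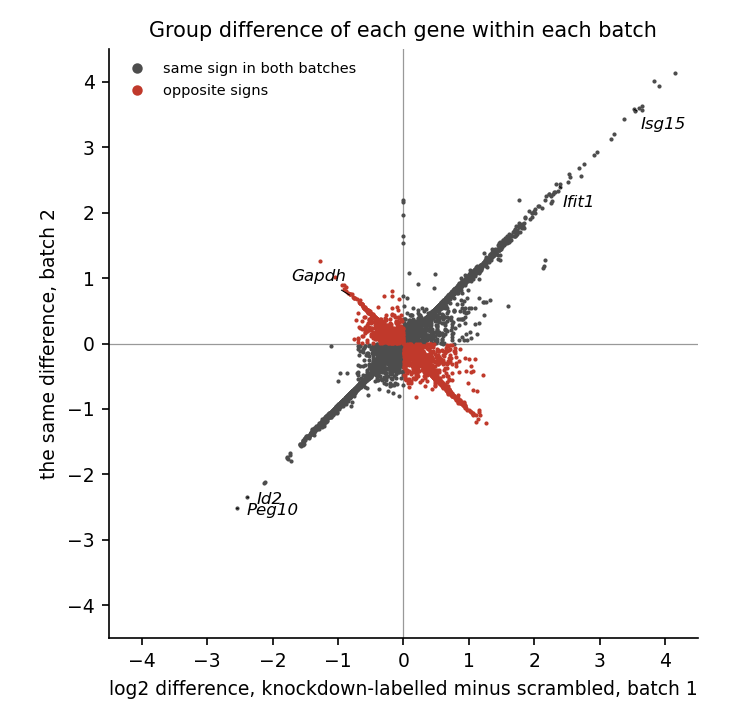
Log2 difference between the libraries labelled knockdown and scrambled in batch 1 (horizontal axis) and batch 2 (vertical axis) for each of 8750 tested genes; grey points have the same sign in both batches and red points opposite signs. In all, 6519 genes had the same sign, and the points of opposite sign lie along the falling diagonal.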

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

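Of the tests in this part, those on exchanged group labels, on reads shared between Ifit genes, on values exchanged after normalization, on shared fragments within a group and on an independent second difference were chosen after the result they measure was seen, and the test on genes annotated to respond to type I interferon after the Reactome test had missed.

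In all, 1390 genes differed between the groups in both batches, in opposite directions, by more than 3 counting SDs in each. The differences between the batches given in this part were not tested. Changes of opposite sign in the batches were also seen in Gapdh (log2 change -0.77 in batch 1 and 0.71 in batch 2), Mef2a (-0.05 and 0.10) and Tug1 (0.18 and -0.38). List medians of opposite sign in batch 1 and batch 2 were those of angiogenic and paracrine factors (0.35 and -0.29), ATF4 and integrated stress response genes (0.31 and -0.20), extracellular matrix genes (0.06 and -0.27), glycolysis and hypoxia genes (-0.26 and 0.36), immediate-early stress genes (0.23 and -0.26), senescence and growth arrest genes (0.02 and -0.09) and smooth muscle contractile genes (-0.19 and 0.12).

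In the genes of opposite direction, the library labelled scrambled 1 was close to that labelled knockdown 2 and scrambled 2 to knockdown 1. An exchange of 1 batch's values after normalization is argued against, since of 1319 genes with opposite changes of at least 0.2 (log2) in each batch 99.7% were whole fragments with their own library's depth and 0.5% with exchanged depths, and so is an exchange of fragment numbers before it, since in those genes the matched libraries differed by medians of 0.015 and 0.029 where the depth ratios are 0.11 and 0.29. Fragments shared within a group stay open: 21.6% and 22.3% of genes differed within a group by more than 3 counting SDs, but the crossed pattern itself needs such genes, and at 300 to 1000 fragments 36.9% of genes in the libraries labelled scrambled (14.6% simulated) and 26.8% in those labelled knockdown (15.8% simulated) lay within 0.2 counting SDs, against 25.5% (15.5% simulated) and 14.8% (15.7% simulated) over all genes and 10.6% (16.4% simulated) and 3.9% (16.4% simulated) from 5000 fragments. A second difference independent of the group would have left 1628 genes with both a group and a crossed difference, and 645 were seen, a ratio of 0.40. What made the pattern stays undetermined, and no biological explanation was tested.

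Ifit1 and 22 of 23 tested interferon-stimulated genes were higher in the libraries labelled knockdown. Reads shared between Ifit genes stay open for Ifit1 itself: the 22 genes are no Ifit genes but belong to the pattern, so their rise does not test it. Exchanged group labels and an interferon response of the cultures labelled knockdown stay open, cannot be told apart and may both hold. The ratio of Ifit1 between the libraries labelled scrambled and knockdown was 0.13, which restates the result and so tests neither. No other value names the construct. A different origin of the cells was not tested and stays open too. Y-linked genes were at 0.01% and 0.00% against 1.40% and 1.45% of their X-linked partners' summed FPKM. Of 56 other genes under Reactome interferon terms 16 rose and 31 fell, and of 28 others annotated to respond to type I interferon 10 rose and 7 fell, with p of limma's camera of 0.27 (downward) and 0.083 (upward). Both predictions had set such a p against an interferon response, which was too strict, because many of the Reactome genes are signalling parts that interferon need not induce and a p that misses the threshold shows no absence.

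More ribosomal protein and oxidative phosphorylation genes were higher than lower in the libraries labelled knockdown, and both lists passed with camera's preset correlation but not with an estimated correlation (adjusted p = 0.73 each) or after quantile normalization (0.65 and 0.053), nor ribosomal proteins with fry (0.11). A GC content trend as the whole cause is argued against, since both lists passed after it was taken out (adjusted p = 3.1e-05 and 1.3e-04). Gene length bias stays open as a candidate explanation: after the length trend was taken out, the ribosomal protein list had adjusted p = 0.99 and a median of -0.19 (SD 0.54 over genes) from 0.12 (SD 0.51), and the oxidative phosphorylation list 0.62 and -0.10 (SD 0.44) from 0.28 (SD 0.49), so the calls ended because the medians moved and not because the spread grew. The interferon-stimulated genes passed before and after (adjusted p = 1.2e-10 after). A biological difference between the groups that follows transcript length stays open and was not tested.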

How the results depend on the processing

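In this part, the crossed block, the counting-error floor and limma-voom were chosen after the data were seen. The replicate block gave 2205 higher and 3417 lower genes, and among the named genes and lists it ended the call of Gata6 (adjusted p = 0.11) and no other. Higher genes numbered 3819 without a filter, and 1583 higher and 2213 lower (3796 in all) were found at a mean FPKM of at least 5, where fewer genes were tested. With a log2 change of at least 1 there were 412 and 355, 767 in all. The counts under every other setting stayed within 1.5 times those reported, and the crossed block, a pairing seen in the data, gave 2962 higher and 4282 lower. With an estimated correlation 0 lists passed: adjusted p was 0.86 for cell cycle, 0.8 for Ifit and 0.73 for ribosomal protein, oxidative phosphorylation, interferon-stimulated and stromal genes. That setting rests on few degrees of freedom, so its misses decide little. With quantile normalization adjusted p was 0.65 for ribosomal proteins, 0.053 for oxidative phosphorylation and 0.0045 for translation factors (0.0015 without a filter). With fry it was 0.081 for cell cycle, 0.11 for ribosomal proteins, 0.0073 for cardiac, 0.0021 for epithelial, 0.0041 for senescence, 0.0044 for Wnt and 0.028 for translation factors. Leaving out each library, which assumes the lone library to vary like the other group, gave 0.0081 to 0.11 for cell cycle, 0.038 to 0.19 for translation factors and 0.71 to 0.98 for smooth muscle. Directions turned, none past the threshold, for extracellular matrix (0.94 at a mean FPKM of at least 5, 0.19 with fry), immediate-early (0.89 without a filter, 0.95 at a mean FPKM of at least 5, 0.93 with fry), skeletal myogenic (0.89 without a filter) and smooth muscle genes (0.93 median-centred, 0.7 quantile, 0.34 with fry, 0.9 without scrambled 2, 0.98 without knockdown 2). Log2 changes turned in Gapdh (0.14 median-centred, 0.02 with voom, -0.40 to 0.35 leaving out a library, turned without scrambled 1 or knockdown 1), Gata6 (0.01 median-centred), Tug1 (0.07 median-centred, -0.25 to 0.05 leaving out a library) and Mef2a (-0.02 to 0.07 leaving out a library), the last 2 without scrambled 2 or knockdown 2. The mean of the median differences within groups, 0.027, was 0.032 with a pseudocount of 0.1, 0.023 without a filter, 0.049 median-centred and 0.050 after quantile normalization, and 59.7% of genes had the same sign in both batches without a filter and 76.3% median-centred, from 74.5%. Beyond fewer genes or libraries, the cause was not tested. With the counting-error floor 8 named genes no longer passed. That floor is the counting error of log2 fragments, while the changes are on log2(FPKM + 1), which shrinks those of low genes. It is therefore too strict at low FPKM, and a call lost there need not come from depth. With limma-voom, 1 named gene with recovered fragments no longer passed. The planned test on counts was not run.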

Other observations

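Of the observations in this part, the Reactome scan and the Y-linked genes were chosen after the data were seen. Genes of cholesterol biosynthesis were higher in the libraries labelled knockdown, with 15 of 24 tested members up and 0 down (median log2 0.53, with 0.56 in batch 1 and 0.59 in batch 2, camera adjusted p = 0.0031; adjusted p = 1 with an estimated correlation). Mvd and Mvk, enzymes of the mevalonate pathway, rose from mean FPKM of 48.2 and 31.1 to 124 and 74.5, and Msmo1, a sterol oxidase, from 5.18 to 12.6. Genes of immunoregulatory interactions had 16 of 18 members up and 2 down (adjusted p = 0.0031; adjusted p = 1 with an estimated correlation), among them the class I histocompatibility gene H2-K1, from 3.69 to 11.3. Genes of the major splicing pathway were lower, with 118 of 188 down and 23 up (median -0.47, adjusted p = 0.0098; adjusted p = 1 with an estimated correlation), such as Ddx23, a spliceosome helicase, from 56.8 to 19.5, and Sf3a3, a U2 particle protein, from 62.8 to 24.8. Genes of mature transcript export to the cytoplasm had 49 of 74 down and 7 up (median -0.51, adjusted p = 0.014; adjusted p = 1 with an estimated correlation), such as the export receptor Nxf1, from 22.9 to 9.31. Hippo signalling genes had 15 of 18 down and 0 up (median -0.63, adjusted p = 0.018; adjusted p = 1 with an estimated correlation), among them its effector Yap1, from 27.4 to 10.9. In all, 27 of 810 terms passed, 10 upward and 17 downward, and 0 with an estimated correlation. This last setting rests on few degrees of freedom, so its misses decide little. After the length trend was taken out, adjusted p was 8.6e-04 for cholesterol biosynthesis, 0.0016 for immunoregulatory interactions, 6.6e-04 for splicing, 0.0011 for transcript export and 0.061 for Hippo signalling. Medians after that step were not taken, so whether the Hippo change shrank is not known.

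Of the Y-linked genes, Ddx3y had 1 and 0 fragments in the libraries labelled scrambled and 99 and 141 in those labelled knockdown. Together Ddx3y, Eif2s3y, Kdm5d and Uty had 3 and 1 fragments against 252 and 307, which was 0.01% and 0.00% against 1.40% and 1.45% of the summed FPKM of their X-linked partners. Whether the cells of both groups had the same origin is not stated. A different origin would coincide with the groups, so any difference between them could come from it, which was not tested.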
